A study of Mus musculus with 22 samples.

How the data were processed

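H3K27me3, the histone mark laid down by Polycomb repressive complex 2 (PRC2), was mapped by CUT&RUN in mouse retina at embryonic day 18.5. In CUT&RUN a nuclease tethered to an antibody releases the DNA beside the marked nucleosomes. The animals were Jarid2 conditional knockouts (cKO, Jarid2 fl/fl with an inducible Rx-cre) and littermate controls. Per the labels' protocols, Cre was induced at embryonic day 10.5 with tamoxifen at 75 µg per g. Both retinas of an animal were pooled as a sample. The protocol text gives the control genotype as Jarid2 fl/fl, whereas the sample labels give fl/+ for most controls, and the sample labels were used. The work was done in 2 batches. The labels list 22 libraries. The 16 H3K27me3 libraries, from 5 control and 5 cKO animals, were analysed, and the 6 IgG libraries were not analysed here.

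The deposited table gives counts of reads or fragments per peak for 1 set of 19034 peaks, with a column per H3K27me3 library. These counts are called reads here. Per the submitters' processing notes, Novoalign 4.02.02, SAMtools, MACS2, DESeq2 1.38.1 and the mouse build mm10 were used, with no role or order given. The settings of the peak caller, the read counter, the treatment of duplicate reads and the use of the IgG libraries are not given in the sources used here. Per the file headers, the authors also deposited a mean signal per peak, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value, but the headers do not name the contrast. The deposited annotation gives each peak a gene and a distance from a transcription start site (TSS) of that gene, and was used as deposited. Which libraries the peaks were called on is not given in the sources used here. RefSeq gene bodies came from GRCm38.p6, the assembly that mm10 represents. Of 4208 peaks that the annotation placed at the TSS of a protein-coding gene found in RefSeq, 97.5% overlapped that gene there.

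In batch 2 each animal had 2 technical duplicates. The 6 pairs of duplicates differed by no more than counting noise (chi-square per degree of freedom 0.88 to 0.997), so their counts were summed and each animal was counted as 1 sample. Pairs of different animals of a group and batch, with duplicates summed, gave 1.05 to 2.53. An animal held 1688368 to 2864080 reads in peaks.

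Peaks with low counts were removed with filterByExpr, which left 16307. TMM factors were computed, and edgeR 4.0.16 quasi-likelihood tests (glmQLFit and glmQLFTest, R 4.3.3) were run with batch as an additive term and Benjamini-Hochberg adjustment. A peak was called at an adjusted p under 0.05. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. Log2 CPM used a prior count of 2. For genes, the counts of all peaks assigned to a gene were summed and tested in the same way over 11324 genes. Lists of genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. The Foxp1 locus also had an exact two-sided permutation test of log2 CPM that exchanged animals within batches. Fisher's exact test compared the places of called and uncalled peaks. DESeq2 1.42.0 was run as an alternative test and to refit the deposited contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

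The steps were tested on simulated data drawn from the means and totals of these animals. Of 16307 peaks, 100 were changed 1.5-fold and 100 were changed 2-fold. Of these, 51% and 88% were called, and 14 other calls (9.15% of all calls) were false. With sums per gene over 11324 genes, these shares were 65% and 92%, with 1 false call. A simulated batch by genotype test with no true difference made 0 calls with edgeR over 16307 peaks. In these simulated data, peaks changed 1.5-fold were thus missed about as often as found at this depth and number of animals. Smaller changes were not simulated. Far fewer peaks were changed there than the 1442 called in the real data, which makes the adjustment stricter, so the shares found may differ in the real data.

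The design, the 22 gene lists, the rule for named genes and most alternative settings were set before the data were examined. Named peaks were every tested peak assigned to Foxp1 and Jarid2, and the 10 lower and 10 higher peaks with the smallest adjusted p that went the same way in both batches, with 1 peak per gene. From each list with at least 3 measured genes, up to 3 genes with the smallest p were named. 1 gene that this rule names is not reported here, but it was kept in all tests. The alternative settings set beforehand were other scalings, no filter on low counts, no batch term, a replicate block, sex as a further term, each batch alone, each technical duplicate alone, DESeq2 and limma-voom, autosomal peaks, leaving out each animal in turn, other thresholds, other TSS windows, and other settings of the list tests. Settings chosen after seeing the data were offsets for a trend with reads per kb, counts thinned to a common total, gene lists by RefSeq gene body overlap, and alternatives for the batch by genotype test.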

Results

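Counts of H3K27me3 CUT&RUN reads in 19034 peaks were available for the retinas of 10 mice at embryonic day 18.5, 5 with Jarid2 deleted in retinal progenitors (cKO) and 5 controls. Jarid2 is an accessory subunit of PRC2. Batch 1 held 2 cKO and 2 control animals of both sexes, and batch 2 held 3 cKO and 3 control animals, all male. The control animals carried 1 or 2 floxed alleles without Cre, except control replicate 1, which was heterozygous for the floxed allele and carried Cre. Reads in peaks per animal ran from 1688368 (control replicate 2) to 2864080 (control replicate 3). The peaks had a median width of 2791 bp, and 49.4% were annotated as promoter.

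The single tested peak assigned to Jarid2 (chromosome 13, 44728300 to 44729290, mm10, promoter) held 4.45 ± 0.46 CPM in controls and 4.38 ± 1.74 CPM in cKO (SD, n = 5 each), a log2 fold change of -0.071 ± 0.27 (SE, edgeR adjusted p = 0.929). Its level in single animals ran from 2.67 CPM (cKO replicate 4) to 6.40 CPM (cKO replicate 1). H3K27me3 at a promoter does not measure the deletion, so this peak does not check the genotype labels. The sex labels could be checked on the X chromosome, since the inactive X of females carries H3K27me3. X-linked peaks took 2.41% and 2.51% of the reads in the female animals, cKO replicate 1 and control replicate 2, and 1.23% to 1.33% in the 8 males. The mean log2 CPM of X-linked peaks minus that of autosomal peaks was 0.22 and 0.35 in the females and -0.80 to -0.68 in the males.

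The main comparison asked where H3K27me3 in the retina depended on Jarid2. In cKO retinas H3K27me3 was lower along the gene of the transcription factor Foxp1, near Lmo4 and within introns of Klf12 and Mecom, while the other 7 of the 10 lower peaks with the smallest adjusted p lay 51.7 to 303 kb from any protein-coding gene in RefSeq. It was higher at fewer sites, such as the promoters of Adra1d, Art3 and Nab2. Of 16307 tested peaks, 1204 were lower and 238 higher in cKO (edgeR quasi-likelihood test, adjusted p under 0.05), so 83.5% of the 1442 called peaks were lower. The lower peaks fell by a median of 1.46-fold and at most 3.46-fold, and the higher peaks rose by a median of 1.35-fold and at most 2.15-fold. A change of 2-fold or more was seen at 91 lower and 2 higher peaks. With the total count in place of TMM factors, 1013 peaks were lower and 467 higher (68.4% lower), and with DESeq2 776 were lower and 21 higher (97.4% lower). Without a batch term 364 peaks were called. In batch 2 alone 964 peaks were lower and 170 higher. In batch 1 alone, with 2 animals per genotype, edgeR called 0 peaks, with 1828 at an unadjusted p under 0.05, or 46 lower peaks over the peak set of all animals. The number of higher peaks dropped to 137 without cKO replicate 2, 142 without cKO replicate 4, 110 without cKO replicate 5, and 140, 136 and 130 without control replicates 2, 3 and 4.

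The Foxp1 locus was the subject named in the title of the study. Foxp1 encodes a forkhead transcription factor. H3K27me3 summed over its 8 peaks was 425 ± 126 CPM in controls and 238 ± 116 CPM in cKO (SD, n = 5 each), where the SD includes the difference between batches. The log2 fold change was -0.92 ± 0.11 (SE, edgeR adjusted p = 3.1e-05). The exact two-sided permutation test within batches gave p = 0.0167, which is the smallest its 120 arrangements allow. All 5 cKO animals lay below the control mean of their batch at each of the 7 called peaks. The sum was 2.65-fold lower in batch 1 and 1.59-fold lower in batch 2. This difference between batches did not pass the threshold over all genes (edgeR test of the interaction, adjusted p = 0.209, unadjusted p = 1.8e-04). Since Foxp1 was named beforehand, a difference in size between the batches stays open.

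**Figure D1:**
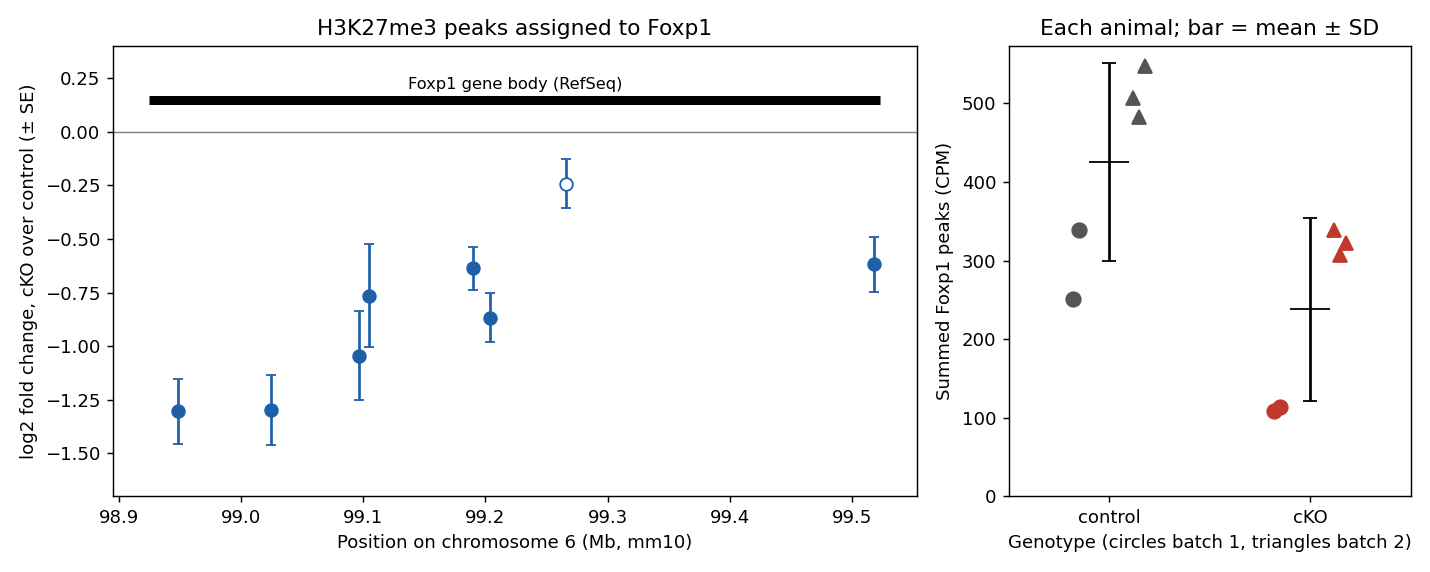
H3K27me3 at Foxp1. Left, log2 fold change of cKO over control with its SE at each of the 8 peaks against position on chromosome 6, filled where the adjusted p was under 0.05, with the RefSeq gene body as a black bar. Right, summed CPM of the 8 peaks per animal with mean and SD (n = 5 per genotype), where controls averaged 425 and cKO 238.

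Within the gene, the largest decreases were at the lower-coordinate end of the locus. The peak at chromosome 6, 98943380 to 98953270, annotated as exonic, fell from 106 ± 41.0 to 44.3 ± 29.3 CPM (log2 fold change -1.30 ± 0.15, edgeR adjusted p = 1.4e-05). A peak at 99023470 to 99025900, near an annotated TSS, had a log2 fold change of -1.30 ± 0.16. The intronic peak at 99198980 to 99209210, the Foxp1 peak with most reads, fell from 148 ± 45.3 to 83.6 ± 43.8 CPM. The promoter peak at 99515160 to 99520600 had a log2 fold change of -0.62 ± 0.13 (adjusted p = 0.00279), whereas the promoter peak at 99263470 to 99268550 did not pass the threshold (-0.24 ± 0.11, adjusted p = 0.223). The intronic peak at 99103840 to 99105900 was close to the threshold (adjusted p = 0.049) and stayed past it in only 2 of the 10 fits that left out 1 animal, those without cKO replicate 4 and without control replicate 5. The highest adjusted p of the others was 0.163, without cKO replicate 3. This peak also did not pass with DESeq2 (0.25), in batch 2 alone (0.236) or with the first duplicate only (0.224). Nor did it pass with the replicate block (0.0695), the total count (0.0649), no filter (0.0603) or thinned counts (0.0958). Without a batch term, the 7 peaks did not pass, and the summed Foxp1 signal had a log2 fold change of -0.84 (adjusted p = 0.146), and in batch 1 alone it was -1.39 (adjusted p = 0.0715).

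The 10 lower peaks with the smallest adjusted p were intronic or intergenic, apart from a peak annotated as exonic and assigned to Gm8649. The peak in Klf12, which encodes a Krüppel-like factor (chromosome 14, 100066620 to 100074340, intron), fell from 78.9 ± 30.1 to 30.7 ± 16.4 CPM (log2 fold change -1.37 ± 0.14, edgeR adjusted p = 6.4e-06, lower in 5 of 5 cKO animals). The peak near Lmo4, a LIM-domain transcriptional regulator (chromosome 3, 144173170 to 144179940, intergenic), had a log2 fold change of -0.99 ± 0.09. An intronic peak of Mecom, a zinc-finger transcription factor gene, was assigned to Gm38362 (chromosome 3, 30346500 to 30351790) and fell from 64.2 ± 24.3 to 32.2 ± 14.9 CPM. All 10 were lower in 5 of 5 cKO animals. The largest fold among the 10 was at an intergenic peak assigned to Gm22074 (chromosome 3, 6880660 to 6893300), which fell from 129 ± 49.8 to 43.9 ± 19.1 CPM. The others were intergenic peaks assigned to Gm22967, Gm7328, Gm5183, Gm13751 and Gm13531, with log2 fold changes from -0.76 to -1.06, and the Gm8649 peak at -0.82. For these, the nearest protein-coding gene in RefSeq was 51.7 to 303 kb away, Hand2 being the most distant. Without a batch term, 6 of the 10 did not pass, among them Lmo4 (adjusted p = 0.0669), the Mecom peak (0.0965) and Klf12 (0.0523).

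The 10 higher peaks changed less. The peak at the promoter of Art3 (chromosome 5, 92387230 to 92395300) rose from 117 ± 16.6 to 162 ± 30.5 CPM (log2 fold change 0.46 ± 0.08, edgeR adjusted p = 7.7e-04, higher in 5 of 5 cKO animals). Promoter peaks of Adra1d, an adrenergic receptor gene, Nab2, a co-repressor gene, Adgra2, Espn, Gorab and Nxph4 had log2 fold changes of 0.32 to 0.46. The peak in the 3' UTR of Lrrc25 had 0.56, and the intergenic peaks assigned to Kbtbd2 and Gata6 had 0.44 and 0.71. Gata6 encodes a GATA transcription factor, and this peak lay 217 kb from its gene body and did not pass with DESeq2 (adjusted p = 0.0685). All 10 were higher in 5 of 5 cKO animals, and 6 of the 10, among them Adra1d (adjusted p = 0.274) and Art3 (0.0566), did not pass without a batch term. The Nab2 peak also overlapped the gene Stat6, and the Espn peak the gene Tnfrsf25.

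Lower and higher peaks lay in different parts of the genome. Of the lower peaks, 29.6% lay within 2.5 kb of a TSS, against 52.2% of the 14865 uncalled peaks (Fisher's exact test, two-sided, odds ratio 0.384, 95% confidence interval 0.337 to 0.437, adjusted p = 5.5e-52). Lower peaks were more often in the rest of gene bodies (31.2% against 16.3%) and between genes (39.2% against 31.4%), the latter also at 5 kb. At 1 kb the shares between genes were 42.0% and 42.1%. That window counted peaks annotated as promoter but more than 1 kb from a TSS as between genes, so it does not test this difference. Of the higher peaks, 63.4% were within that distance of a TSS (odds ratio 1.59, adjusted p = 9.6e-04), but with a window of 1 kb the odds ratio was 0.885 (adjusted p = 0.467). Lower peaks had a median width of 5841 bp, higher peaks 4811 bp and uncalled peaks 3211 bp, and wider peaks with more reads are easier to call. Neighbouring peaks are not independent, so these p-values are too small.

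**Figure D2:**
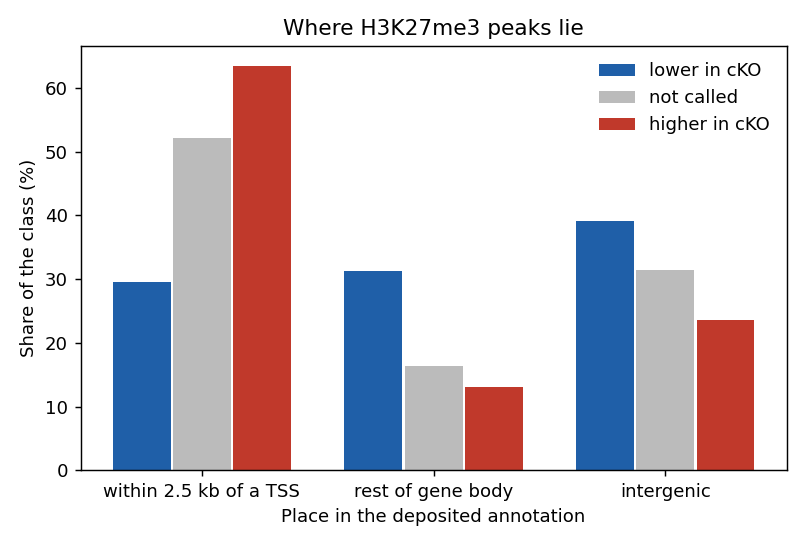
Share of peaks (%) by place in the deposited annotation, for peaks lower in cKO (n = 1204), not called (n = 14865) and higher in cKO (n = 238). Lower peaks were within 2.5 kb of a TSS in 29.6% of cases, uncalled peaks in 52.2% and higher peaks in 63.4%.

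The change was compared between the batches, of which batch 1 held both sexes and batch 2 males. Of the called peaks, 1438 (99.7%) had the same sign in both batches, against 63.2% of uncalled peaks. Calls were made on both batches together, which favours a shared sign. Over the called peaks, which are not independent replicates, the log2 fold changes of the batches had a Pearson r of 0.81 and a Spearman rho of 0.71. A test of the difference in genotype effect between batches called 2 peaks (edgeR, adjusted p = 0.042 for both), in the 3' UTR of Parn and in a promoter peak assigned to Gm15556 that overlaps Foxp4. The Foxp4 peak had a log2 fold change of -2.03 in batch 1 and -0.39 in batch 2, and the Parn peak -1.61 and -0.17. In all, 642 peaks had an unadjusted p under 0.05. Without cKO replicate 1, 3 or 4 or control replicate 4 or 5, edgeR called 0 peaks, with 449 to 645 at an unadjusted p under 0.05. It called 6 without cKO replicate 2, 3 without cKO replicate 5, 5 without control replicate 1, 5 without control replicate 2 and 1 without control replicate 3. No other tool was run for this difference.

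**Figure D3:**
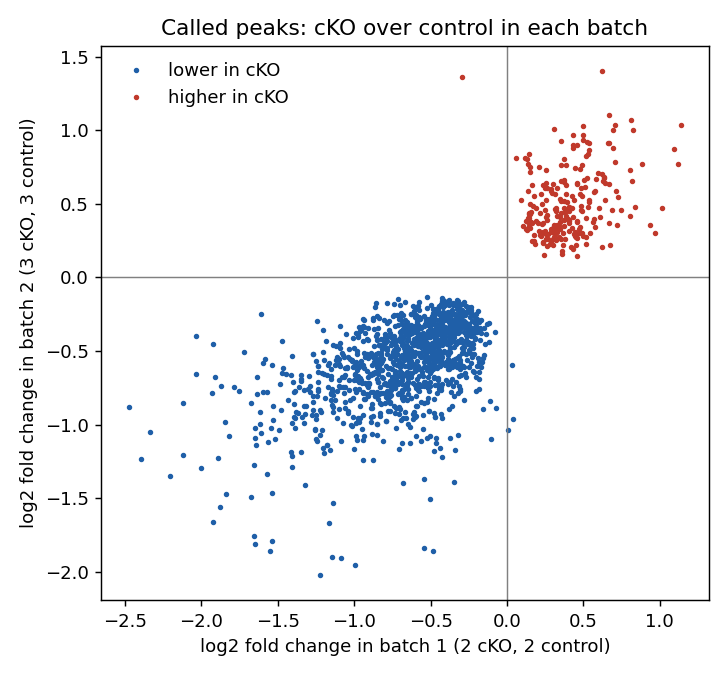
Log2 fold change of cKO over control in batch 1 (x axis) and batch 2 (y axis) for the 1442 called peaks, coloured by direction. Of these, 1438 have the same sign in both batches.

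Summed per gene, H3K27me3 was lower at 939 and higher at 168 of 11324 genes (edgeR, adjusted p under 0.05). The genes higher numbered 105, 102 and 93 without cKO replicates 2, 4 and 5, and 99 and 91 without control replicates 3 and 4, and 470 with the total count in place of TMM factors. Among lists with at least 3 measured genes, that of early retinal progenitors had the largest share of decreases with the deposited annotation. With RefSeq gene bodies, the list shared by progenitors of all stages did, with 1 of 3 genes. Of the 16 measured early progenitor genes, 6 fell, and 6 fell when adjusted over the list alone, against 5 with DESeq2, 5 with limma-voom and 4 with RefSeq gene bodies. Besides Foxp1 these were Lin28b, an RNA-binding regulator of developmental timing (log2 fold change -0.26 ± 0.06), the nuclear receptor gene Nr2f2 (-0.27 ± 0.07) and, named after their values were seen, Zic5 (-0.34 ± 0.09), Lin28a (-0.38 ± 0.11) and Ikzf1 (-0.18 ± 0.06). The list passed camera (adjusted p = 0.0165) but not with an estimated correlation (adjusted p = 0.895), and fry gave an adjusted p of 0.159 for a shift in 1 direction and 0.00988 for change in either direction. The latter also passed for the ganglion cell list (0.034) and the photoreceptor list (0.00129). The early progenitor list did not pass camera without cKO replicate 1 (adjusted p = 0.0776), cKO replicate 5 (0.113), control replicate 1 (0.117) or control replicate 3 (0.0646). In 72 of 100 splits of the animals, the real one included, at least 1 list passed camera, so chance is not excluded for this list. With camera the other lists had adjusted p from 0.0739 to 0.981. In batch 2 alone the early progenitor list did not pass (adjusted p = 0.178), nor did Lin28b (0.101) and Nr2f2 (0.0932), and without a batch term Lin28b had an adjusted p of 0.0772 and Nr2f2 of 0.101. Ikzf1 did not pass with genes assigned by RefSeq gene bodies (0.0564).

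Some regulators of retinal cell types had lower H3K27me3, as did 939 of all 11324 genes. None of the lists in this paragraph passed camera in the main fit, so no preference for such regulators was shown. Atoh7, needed for ganglion cells to form, fell from 167 ± 43.7 to 99.1 ± 35.3 CPM (log2 fold change -0.77 ± 0.09, edgeR adjusted p = 2.7e-05), and in the ganglion cell list 2 of 22 measured genes fell, the other being Rbpms (-0.53 ± 0.14, adjusted p = 0.0203; DESeq2 0.182). Gap43 had -0.23 ± 0.08 (adjusted p = 0.068). Otx2, a homeobox gene of photoreceptor precursors, fell from 731 ± 69.2 to 580 ± 29.0 CPM (-0.33 ± 0.07, adjusted p = 0.00222) and was the only 1 of 14 photoreceptor genes past the threshold, beside Gnat1 (0.38 ± 0.13, adjusted p = 0.064), which rose when adjusted over the list alone, and Neurod1 (-0.16 ± 0.06, adjusted p = 0.0908). Meis2 fell among 16 amacrine genes (-0.23 ± 0.06, adjusted p = 0.0223), where Th and Barhl2 had -0.21 and -0.15, and Bhlhe22 among 9 bipolar genes (-0.21 ± 0.06, adjusted p = 0.0419), where Trpm1 and Isl1 had -0.20 and -0.076. Lhx2 fell among 4 genes shared by progenitors of all stages (-0.26 ± 0.07, adjusted p = 0.0203), where Hes1 and Ccnd1 had -0.45 and -0.19. Of 9 late progenitor genes and 7 horizontal cell genes, 0 passed with edgeR, DESeq2 or limma-voom, and 3 and 0 had an unadjusted p under 0.05 with edgeR, with Id2 at -0.49 ± 0.18, Nfix at 0.13, Nfia at -0.14, Onecut1 at -0.12, Onecut2 at -0.11 and Lhx1 at -0.078. With genes assigned by RefSeq gene bodies, chosen after seeing the data, Nfix rose (0.15, adjusted p = 0.0195) and Bhlhe22 did not pass (0.0776). In the ganglion cell list that assignment had 3 genes lower and 1 higher, and the 2 added, named after their values were seen, were Ebf3 (-0.17, adjusted p = 0.0339) and Irx5 (0.25, adjusted p = 0.00405). The calls of Rbpms, Meis2, Bhlhe22 and Lhx2 were not kept in every fit without 1 animal. Rbpms held only without cKO replicate 1 or control replicates 1, 2 or 5 (adjusted p up to 0.0781, without cKO replicate 5). Meis2 held only without cKO replicates 3 or 4 or control replicates 1 or 5 (up to 0.0788, without control replicate 2). Bhlhe22 held only without cKO replicate 1 or control replicates 1 or 5 (up to 0.129, without control replicate 3). Lhx2 was lost without cKO replicates 1, 2 or 5 or control replicates 2 or 4 (up to 0.073, without cKO replicate 1), and Nr2f2 without cKO replicate 1 (0.0595) or control replicate 3 (0.0525). Without a batch term Otx2 passed, but Atoh7, Rbpms, Meis2, Bhlhe22 and Lhx2 did not, and in batch 2 alone Lhx2 (adjusted p = 0.36) and Meis2 (0.108) did not. With the first duplicate only, Lhx2 (0.0547), Meis2 (0.0578) and Bhlhe22 (0.101) did not pass, and with the second, Rbpms (0.0628) and Bhlhe22 (0.0706). With DESeq2, Lhx2 (adjusted p = 0.0566) and Rbpms did not pass, and with the total count Lhx2 (0.0525) and Bhlhe22 (0.082) did not.

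Few developmental genes outside the retinal lineage passed the threshold singly. Log2 fold changes were negative for 50 of 56 non-neural transcription factors and 45 of 47 of other parts of the nervous system. The medians of these lists were -0.038 and -0.057, and camera gave adjusted p of 0.324 and 0.0739, so they were not shown to be spared. Of 56 transcription factors of non-neural tissues, 0 passed with edgeR, DESeq2 or limma-voom and 5 had an unadjusted p under 0.05, with Tbx20, Tbx15 and Tbx3 at -0.20, -0.16 and -0.17. With genes assigned by RefSeq gene bodies, Tbx20 (-0.18, adjusted p = 0.037) and Tbx15 (-0.14, adjusted p = 0.0394) fell. Of 47 transcription factors of other parts of the nervous system, Pou3f1 fell (-0.50 ± 0.15, adjusted p = 0.0394) and 0 passed when adjusted over the list alone. In that list 3 genes, Pou3f1 included, had an unadjusted p under 0.05, and Lmx1b and Sim1 had -0.15 and -0.13. Among 48 signalling genes, the ligand genes Wnt5b (-0.57 ± 0.14, adjusted p = 0.0119) and Wnt5a (-0.25 ± 0.06, adjusted p = 0.0127) and Fst, which encodes follistatin (-0.37 ± 0.11, adjusted p = 0.0319), fell. Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, fell from 52.7 ± 10.4 to 39.8 ± 12.4 CPM (-0.41 ± 0.10, adjusted p = 0.0133), beside Cdkn2c at -0.075 and Cdkn1a at 0.12. Pou3f1 held only without cKO replicate 5 or control replicates 4 or 5 (adjusted p up to 0.15, without control replicate 3), and Fst only without cKO replicate 3 or control replicates 4 or 5 (up to 0.0975, without control replicate 3). With DESeq2, Pou3f1 (adjusted p = 0.132) and Wnt5b (0.0987) did not pass, and in batch 2 alone Pou3f1 (0.145), Wnt5b (0.148), Fst (0.335) and Cdkn1c (0.0771) did not. Without a batch term none of these 5 genes passed, with adjusted p of 0.267 for Pou3f1, 0.102 for Wnt5a, 0.109 for Wnt5b, 0.259 for Fst and 0.272 for Cdkn1c. Pou3f1 also did not pass with the total count (0.0605) or with the second duplicate only (0.256), nor Wnt5b with the first (0.118), and with RefSeq gene bodies Pou3f1 had 0.228, where Lmx1a, named after its value was seen, fell (-0.12, adjusted p = 0.0484). With the deposited annotation only 5 of 39 Hox genes were measured, of which 0 passed over all genes with edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and Hoxd1 (0.30 ± 0.10, adjusted p = 0.0768 over all genes) rose when adjusted over the list alone, with Hoxb13 and Hoxb6 at -0.070 and -0.066. With RefSeq gene bodies Hoxd1 had -0.016 (adjusted p = 0.891) and edgeR called 0 of 39 Hox genes, none with an unadjusted p under 0.05 (no other tool was run), so the rise depended on how peaks were assigned. The median of that list (-0.042) and its mean (0.017) differed in sign.

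With genes assigned by the deposited annotation, genes of the Polycomb complexes and markers of other cell types gave 0 calls over all genes with edgeR, DESeq2 or limma-voom in the lists of PRC2 (6 measured), PRC1 (10), clustered protocadherins (4), lens (6), endothelium and pericytes (6), microglia and blood (3), Müller glia (2) and astrocytes (2). With edgeR, 1 gene each of the PRC2, protocadherin and microglia and blood lists had an unadjusted p under 0.05, and 0 of the others. In the PRC2 list Ezh1, Phf19 and Eed had log2 fold changes of 0.68, 0.21 and 0.30, and in the PRC1 list Bmi1 and Cbx2 had -0.066 and -0.078. Of the protocadherins, Pcdhga2 had 0.64 and passed when adjusted over the list alone, Pcdhga10 -0.45 and Pcdhga1 0.15. With RefSeq gene bodies, neighbouring protocadherins share peaks and are not independent. There 31 were measured, and the list rose in camera at the preset correlation (adjusted p = 0.0135). That p is too small for genes that share peaks, and no estimated correlation was run with this assignment, so a rise of the list was not shown. Pcdhga2 had 0.18, Pcdhga10 0.18 and Pcdhga1 0.20, and no single gene passed (adjusted p of 0.171, 0.168 and 0.0906 for these 3). The lens genes Bfsp1, Crybb1 and Cryab had -0.21, 0.24 and 0.048. With RefSeq gene bodies the lens gene Bfsp2, named after its value was seen, fell (-0.28, edgeR adjusted p = 0.0118). The endothelial and pericyte genes Erg, Kdr and Cspg4 had -0.096, 0.17 and 0.089 with the deposited annotation. There the microglia and blood genes Klf1, Cx3cr1 and Spi1 had 0.30, 0.41 and 0.16. Of 2 measured pigment epithelium genes, 1 fell, Mitf, named after its value was seen (-0.19 ± 0.05, adjusted p = 0.0282), and both fell when adjusted over the list alone. With DESeq2 neither passed over all genes, with limma-voom 1 did, and with RefSeq gene bodies both did.

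The fold changes in the authors' deposited table were compared with the genotype effect. A refit of the 16 libraries with DESeq2 and additive terms for batch and genotype gave a batch term, batch 1 over batch 2, that differed from the log2 fold change in the authors' deposited table by at most 1.1e-05. The genotype term of that refit differed from it by a median of 0.21, with a Pearson r of 0.26 across peaks, which are not independent replicates. The 1614 peaks past 0.05 in the authors' deposited table equal in number the 1614 of the refitted batch term, and the refitted genotype term had 1242. At Foxp1, the authors' deposited table gives negative log2 fold changes at all 8 peaks, from -0.44 to -2.20, which are differences between batches. Its test score has the opposite sign to its fold change in 100% of peaks. For these reasons all genotype values given here come from the counts.

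**Figure D4:**
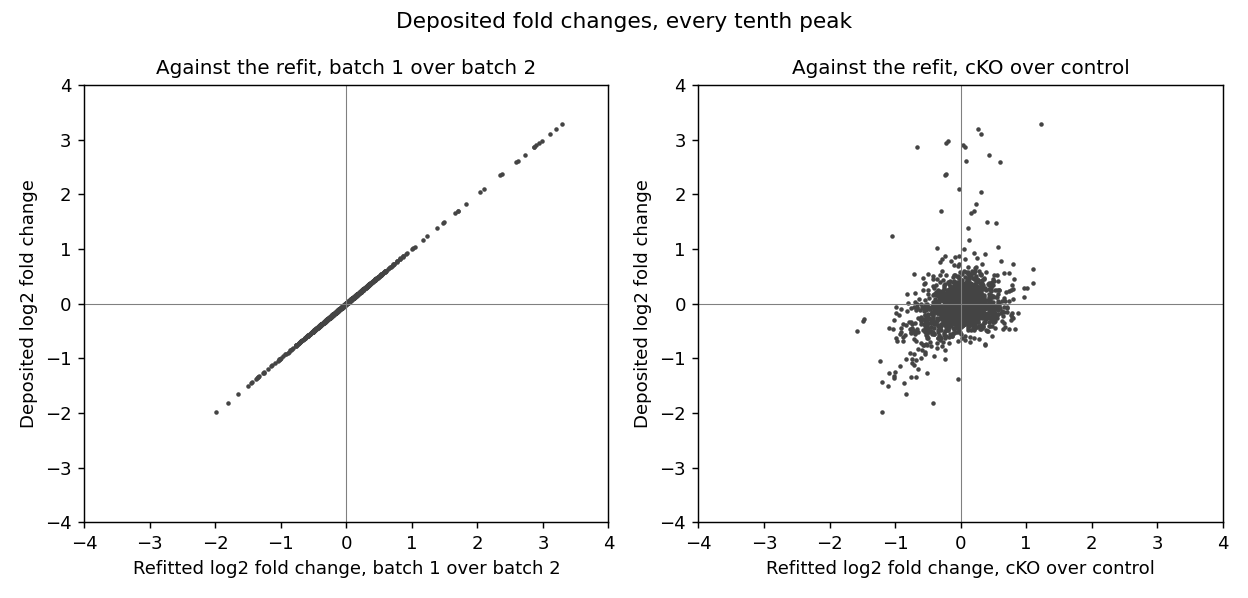
Log2 fold change in the authors' deposited table (y axis) against the refitted batch term (left) and the refitted genotype term (right), for 1 of every 10 peaks. The points lie on the diagonal on the left, where the largest difference over all peaks was 1.1e-05, and spread around 0 on the right, with a Pearson r of 0.26.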

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

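The tests of scaling, of a trend with reads per kb, of depth, of batch 2 alone, of DNA beside Jarid2, of the deposited contrast, of sex, of a deleted Jarid2 copy and of splits with equal batches were chosen only after the results were seen. The fits with other scalings and of batch 2 alone were set beforehand, but not their use as tests of a cause.

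More peaks were lower than higher in cKO, with Foxp1, Lmo4 and Klf12 among the lower. The lowest share of lower calls over 3 scalings was 68.4%, it was 85.8% after thinning to a common depth and 85% in batch 2 alone, all males, and with offsets for a trend with reads per kb 97.3% of the lower peaks stayed called lower, which argues against each of these as the whole cause. Within 10 Mb of Jarid2 11% of tested peaks were called against 8.82% elsewhere (odds ratio 1.28, Fisher's exact test, two-sided, p = 0.376), and 1.11% of all called peaks lay there, which argues against DNA flanking the floxed allele. Of 100 splits of the 10 animals, drawn from 126, only the real 1 called as many peaks (1442). The highest other called 476, with control replicate 1 and cKO replicate 4 exchanged. Of the 51 with 2 animals of batch 1 in each group, as in the real 1, again only that 1 did (highest other 413). Chance is thus unlikely, but so few splits cannot exclude it. Loss of Jarid2 is a candidate explanation and a hypothesis found on these data, and a uniform change of H3K27me3 stays open, since counts scaled to their own total do not show it. The counts also do not separate cell types, so a different mix of cells in cKO was not tested. All cKO animals carried Cre, and among the controls only control replicate 1 did. An effect of Cre itself was therefore not separated from loss of Jarid2.

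For sums per gene, the real split gave 1107 calls and only 1 of 100 splits, the real one, gave as many. The highest other gave 362, or 164 among the 51 with 2 animals of batch 1 in each group, so chance is unlikely here as well. For gene lists past camera, the real split passed 1 and 72 of 100 splits passed as many, the real one included (highest other 13), as did 37 of those 51, so chance cannot be excluded for the early progenitor list.

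Control replicate 1 carried Cre and 1 floxed Jarid2 allele, and stood below the other controls at the Foxp1 peak starting at 99095560 (gap to the nearest animal over the range of the group 0.85), the Foxp1 peak starting at 99515160 (0.783), the Gm22074 peak (0.771) and the sum of Trpm1 (0.777). At 951 autosomal peaks called lower in batch 2 alone, this animal of batch 1 covered 55.5% of the distance from control replicate 2 to the cKO animals of its batch (bootstrap over chromosomes 52.1% to 58.6%). The female and male cKO animals of that batch differed there by -0.034 in mean log2 CPM, which argues against sex. Uncalled peaks matched in width and level differed between the controls by a median of 0.039, against -0.43 at the lower peaks. TMM scaling and the choice of uncalled peaks draw the former towards 0, so it does not decide whether the library was weaker. Deletion of 1 Jarid2 copy may account for the position of control replicate 1. With 1 such animal, this cannot be told apart from variation between animals or from an effect of Cre itself.

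The genotype effect differed between batches at the Parn peak by 1.44 on the log2 scale (batch 2 minus batch 1) and at the Gm15556 peak in Foxp4 by 1.64. The X-linked share of reads set the female apart in the control group (gap over range 0.939) and in the cKO group (0.937). A single animal also stood apart for Ccnd1 (cKO replicate 4, higher, 0.724), Rbpms (control replicate 2, lower, 0.805), Meis2 (cKO replicate 5, lower, 0.825), Barhl2 (cKO replicate 5, lower, 0.754) and Gnat1 (cKO replicate 2, higher, 0.832). In all, 11 of 174 groups of animals had such a gap, and chance gives about 1 in 20, or 8.7. The adjusted p in the authors' deposited table, outside the genotype comparison, passed 0.05 at 1614 peaks, and its fold changes matched the batch term of a refit to within 1.1e-05.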

How the results depend on the processing

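The offsets for reads per kb, the thinning, RefSeq gene bodies and all settings of the test for batch differences were chosen after seeing the data. Foxp1 as a sum of peaks kept its direction under all alternatives run and its call under all but 2: no batch term (-0.84, adjusted p = 0.146) and batch 1 only (-1.39, adjusted p = 0.0715); without 1 animal it ran from -0.98 to -0.80. The replicate numbers do not pair the animals (correlations of same-numbered animals -0.01 to 0.10); with a replicate block 1331 peaks were called, and 4 lists. At the depth and number of animals used here, 51% of peaks changed 1.5-fold were found in simulated data, and the share due to depth was not separated.

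Without a batch term 364 peaks were called (338 lower, 26 higher), with 278 genes lower and 24 higher. Batch 1 only, with fewer animals, gave 0 calls with edgeR, lower or higher, for peaks (1828 at an unadjusted p under 0.05) and genes (1506), and 8 lists. DESeq2 called 797 peaks (776 lower, 21 higher) and 26 genes higher. The total count gave 467 higher peaks, 470 higher genes and 6 batch differences. The technical duplicates alone gave 107 and 116 higher peaks, and the first gave 79 higher genes. An adjusted p of 0.01 left 839 peaks (793 lower, 46 higher), one of 0.1 gave 516 higher, and a log2 fold limit of 0.58 left 604 (546 lower, 58 higher). Batch differences numbered 0 without a filter (edgeR, 674 at an unadjusted p under 0.05) and 7 on autosomes. Lists past camera numbered 2 without a filter, 2 with the second duplicate, 2 with RefSeq gene bodies (where overlapping genes share peaks), 0 in batch 2 only and 0 with an estimated correlation. A 1 kb window turned the odds ratio of higher peaks to 0.885. Except where stated, the cause was not tested.

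Leaving out 1 animal, called peaks ran from 1090 to 1617 (lower 950 to 1366, higher 110 to 288), genes from 734 to 1025 lower and 91 to 241 higher, batch differences from 0 to 6 and lists past camera from 0 to 7.

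Signs turned for results that passed under neither setting. For batch 2 only these were Ccnd1 (0.069), Hoxb6 (0.0012) and Cryab (-0.069), and for batch 1 only Cbx2 (0.00067), Pcdhga10 (0.24) and Cspg4 (-0.083). Without 1 animal, the Jarid2 peak ran from -0.24 to 0.071, Cryab from -0.11 to 0.17 and Cspg4 from -0.018 to 0.16. Over named genes and settings, 1123 values kept direction and side of the threshold, 87 lost a call, 31 gained one and 8 turned; for named peaks these were 652, 61, 0 and 3.

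Lists whose direction turned are given with camera's adjusted p. The Hox list had 0.923 without a filter, 0.632 with the replicate block, 0.0904 in batch 1 only, 0.946 and 0.997 with the first and second duplicate, 0.982 with 1 peak per gene and 0.384 with RefSeq gene bodies. With the total count, non-neural factors had 0.947, signalling 0.929 and PRC1 0.845. In batch 2 only, both of the factor lists, signalling and PRC1 had 0.979. PRC1 had 0.646 with the second duplicate, 0.982 with 1 peak per gene and 0.533 with RefSeq gene bodies. Lens had 0.968 without a filter, 0.999 without a batch term, 0.979 in batch 1 only and 0.791 with 1 peak per gene. Over all fits without 1 animal, turned or not, adjusted p ran from 0.25 to 0.997 for Hox, 1.2e-05 to 0.975 for non-neural factors, 0.00371 to 0.958 for signalling, 0.714 to 0.997 for PRC1, 0.81 to 0.997 for lens and 0.703 to 0.997 for endothelium and pericytes. The values of 1.2e-05 and 0.00371, both without control replicate 5, were not turned: these lists passed downwards there, the direction of the main fit. Over all alternatives, the early progenitor list ran from 5.4e-05 to 0.895.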

Other observations

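All tests and names in this part were chosen after the result was seen. Lower peaks gathered in domains, some of which held developmental genes. Merged where less than 500 kb apart, the 1204 lower peaks formed 616 regions, 17 of them with 7 or more lower peaks. The region with most covered Auts2, a gene linked to neurodevelopment (chromosome 5, 131530220 to 132511280), where 15 of 18 tested peaks were lower. The region from Foxp1 to Prok2 (chromosome 6, 98526150 to 100107830) held 14 lower peaks of 34 tested. Regions with 10 lower peaks held the transcription factor genes Otx2 and Sox5 and the regulator Lmo4, and regions with 7 to 9 included those of Shox2, Zfhx3, Irx1, Vax1 with Emx2, Gbx2 and Nr2f2. A gene in such a region need not be lower itself. Over RefSeq gene bodies Emx2 and Gbx2 did not pass (edgeR, adjusted p = 0.807 and 0.281), whereas Otx2 and Nr2f2 fell as sums of their assigned peaks. A region with 7 of 9 peaks lower lay at Kcnq1 and Cdkn1c (chromosome 7, 143331230 to 143460760). Others of the 17 held Lrmda, Slc7a11, Shisa2 with Atp8a2, or Tfec with Cav1, and whether the domains favour any class of genes was not tested.

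Of peaks at promoters of protein-coding genes, 212 were lower and 113 higher (edgeR), and 8 of the lower fell 2-fold or more. Besides 2 at Foxp1, these 8 were at Micu3 (3.34-fold), Plekha6 (2.64-fold), the protocadherin gene Pcdh7 (2.29-fold), the axon guidance gene Slit2 (2.20-fold), Lnpk (2.13-fold) and the Wnt effector gene Tcf7l2 (2.11-fold). Lower promoter peaks with smaller folds included Flrt3 (1.90-fold), Lmo3 (1.80-fold), Slitrk1 (1.75-fold), Reln (1.66-fold) and Myc (1.63-fold). Among the higher, Cyp2r1 (1.98-fold) and Faf1 (1.94-fold) had the largest folds.

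The gathering was tested by shuffling which peaks were lower within each chromosome. Neighbouring lower peaks less than 100 kb apart numbered 261, against a median of 62 and at most 88 in 1000 shuffles (permutation test, one-sided, p = 0.001, the smallest they can give). The loss may therefore act on stretches of chromatin larger than a peak, as a hypothesis, although peaks of like width and density also lie near each other and this was not separated.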
